A study of Mus musculus with 10 samples.

How the data were processed

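RNA of mouse ES-E14TG2a embryonic stem cells was sequenced in 10 libraries of 5 groups, 2 libraries per group. Per the labels, a Dux transgene was induced with doxycycline, RNA and DNA were extracted together from the same cells, and libraries were made from total RNA with a kit that keeps the strand. Groups and replicate numbers were taken from the sample titles: D1 2C-positive, D2 2C-positive, D2 2C-negative, D4 2C-negative and sgGFP. The labels state neither the event from which days are counted nor how 2C-positive and 2C-negative cells were told apart, and they give no day and no 2C status for sgGFP. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

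The deposited tables hold whole-number read counts, 1 table per library for genes and 1 for repeat subfamilies, with a column without regard to strand and a column for each strand. Per the submitters' processing notes, Trimmomatic 0.36, STAR and edgeR were used with the mouse build mm10. The STAR and edgeR versions, the annotation release, and the way reads were chosen and assigned for the repeat tables are not given in the sources used here. Each gene table had 48442 genes, 2 of them transgenes (SynDux and TdTomato), and 4 entries that name no gene, which stayed out of library sizes and tests. From 22.7% to 72.7% of the reads in a table were assigned to a gene in the column without regard to strand. Symbols and coordinates came from GENCODE M21, whose build GRCm38 is mm10, and 48058 identifiers matched. Repeat tables listed 1067 subfamilies.

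The reverse-strand column was used for genes because the labelled kit is a directional dUTP kit, and the opposite strand held 3.26% to 8.93% of stranded counts. Counts per library ran from 5986009 to 23246058. For repeats the unstranded column was used, a choice made after the files were seen, and counts ran from 812986 to 4457647. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, a robust quasi-likelihood fit of all 10 libraries with a mean per group (5 residual degrees of freedom), and the quasi-likelihood F test of each contrast. Benjamini-Hochberg adjustment ran over the 16930 genes or 933 repeat subfamilies tested within a comparison, and a gene passed at an adjusted p under 0.05. Repeats were scaled by the effective library sizes of the gene tables. Standard errors are the absolute log2 fold change divided by the square root of F. At similar ratios of change to standard error (SE), repeats had far smaller p-values than genes. In D2 against D1 2C-positive cells, the repeat SYNREP_MM (2.08, SE 0.43) had an adjusted p of 0.000301. The gene Duxf3 (1.68, SE 0.36) had 0.0482. Subfamilies also varied together, with estimated correlations of 0.706 to 0.964 within repeat lists. A smaller p-value for a repeat therefore does not mean a more certain change. Levels are CPM (counts scaled to a library of 1e6, TMM-scaled), with the SD over 2 libraries.

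The 18 gene lists and 6 repeat lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A list needed at least 5 measured members. Some genes stood in more than 1 list, such as Gadd45a (decay targets and DNA methylation) and Mycn (Myc targets and pluripotency). The Myc target list also holds Myc. Of the listed members, Gm2022, Dux, Snhg16, MT2B1 and IMPB_01 had no entry under that name. The comparisons, lists, tests, named genes and most alternatives were fixed before the data were examined. Named genes were the 8 with the largest log2 fold change in each direction among those that passed, changed by over 1, averaged at least 5 CPM over the 10 libraries and had both libraries of 1 group above both of the other (leaving out predicted genes and pseudogenes), the 2 members of each list with the smallest adjusted p that passed, and 14 genes named in every comparison. For repeats they were MERVL-int, MT2_Mm and the 4 with the largest change in each direction. SynDux and TdTomato were added after their values were seen. Not every gene the rule names is reported here, though all tests and lists include them.

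The edgeR steps were tested on simulated counts over 16930 genes with the mean levels, library sizes and spread trend of these data. Groups had equal means apart from the changed genes, which were drawn above a minimum level. All groups shared the spread trend, so the distance between the D2 2C-positive replicates was not simulated as such. For 4-fold changes, 81.8% were recovered in the D2 2C-positive against D2 2C-negative contrast, 86.4% in D2 against D1 2C-positive, 87.9% in D4 against D2 2C-negative and 93.9% in sgGFP against D4 2C-negative. For 2-fold changes the shares were 47.8%, 49.3%, 41.8% and 40.3%, and for 1.5-fold changes 4.48%, 4.48%, 2.99% and 11.9%. Over the 933 repeat subfamilies, 60.0% of the 4-fold changes were recovered in the first of these contrasts.

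Alternatives were DESeq2 1.42.0, RLE size factors, library totals without composition scaling, no filter on low counts, the unstranded column, the replicate number as a term, only the 4 libraries compared, leaving out each library, an added 2-fold minimum, and for repeats TMM on their own counts. Nuclear protein-coding genes alone, libraries thinned to 5986009 counts, and a fit of every comparison without D2 2C-positive replicate 1 were added after the data were seen, as were list tests with only the members that had counts in both groups. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the tables and plots. Where a group had 0 counts, a fold was computed against 3 counts over the group and is a lower bound; with 1 to 3 counts a 95% exact Poisson interval of the low count is given. These floors and intervals cover counting error only. The shared replicate numbers were not used to pair libraries in the main tests. The replicates of each group differed by more than sampling noise (chi-square per gene 4.75 to 91.1), so none was treated as the same library.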

Results

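Bulk RNA was measured in ES-E14TG2a cells, a mouse embryonic stem cell line of 129/Ola origin grown in serum with leukemia inhibitory factor. The cells carried a Dux transgene under doxycycline control, and every library was labelled as induced. In the D4 2C-negative libraries the transgene, SynDux, had 0 and 2 sense-strand counts, against 899 or more in every other library. The labels do not state from which event days are counted, so these counts do not decide whether the D4 cells had been induced earlier. Dux is a transcription factor of the early embryo that turns on genes of the 2-cell stage, and stem cells in which these genes are on are called 2C-like. The 10 libraries formed 5 groups of 2: D1 2C-positive, D2 2C-positive, D2 2C-negative, D4 2C-negative and sgGFP. A guide against GFP is a usual non-targeting control, but the labels give neither a day nor a 2C status for sgGFP. The comparisons made were of 2C-positive with 2C-negative cells on D2, of D2 with D1 2C-positive cells, of D4 with D2 2C-negative cells, and of sgGFP with D4 2C-negative cells.

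Stranded counts assigned to genes were 7876627 and 5986009 in the D1 2C-positive libraries (replicates 1 and 2), 6673097 and 9232848 in D2 2C-positive, 23246058 and 22699039 in D2 2C-negative, 16490541 and 21936411 in D4 2C-negative, and 22703532 and 23137303 in sgGFP. A count of 0 in a library allowed a level of up to 0.105 to 0.701 CPM, set at 3 counts. The 4 2C-positive libraries had fewer assigned reads, and a smaller share of their reads fell in genes. On average 30.7% of D1 2C-positive reads and 28.1% of D2 2C-positive reads were assigned, against 64.8% to 72.7% in the other 6 libraries. Unmapped reads made up 19.6% to 24.3% in the 2C-positive libraries and 4.09% to 6.46% in the others. Of uniquely mapped reads, 39.7% (SD 1.18, n = 2) in D1 2C-positive and 45.6% (SD 8.78) in D2 2C-positive lay outside annotated exons, against 12.1% (SD 1.72) in D2 2C-negative, 10.2% (SD 0.622) in D4 2C-negative and 15.3% (SD 0.725) in sgGFP. The non-coding gene Gm26917 had the most counts of any gene in each 2C-positive library.

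**Figure D1:**
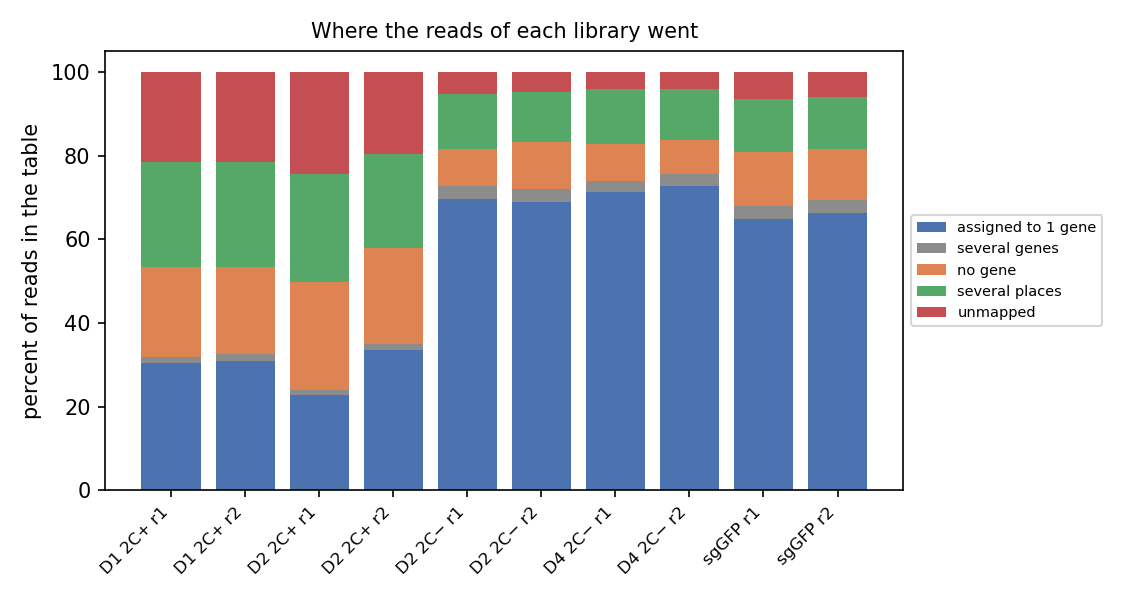
Share of the reads in each gene table that were assigned to 1 gene, fell in several genes, fell in no gene, mapped to several places or did not map, as stacked percentages per library (r1 and r2 are replicates). Unmapped reads were 19.6% or more in each 2C-positive library and 6.46% or less in the other 6.

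The D2 2C-positive replicates lay far apart. Their log2 CPM correlated at r = 0.885 across genes, which are not independent replicates, and 6429 of 13088 genes differed more than 2-fold between them. In the other groups r was 0.973 to 0.994 and 416 to 2178 genes differed that much. On the first 2 principal components, which held 64.1% and 12.6% of the variance, D2 2C-positive replicate 1 lay at −179 and −108 and replicate 2 at −71.9 and 43.3. The mean level of the 2C-like list, as log2(CPM + 1), was 10.24 in replicate 1 and 9.02 in replicate 2. Because all groups share 1 estimate of spread in the test, this distance entered every comparison.

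In D2 2C-positive against D2 2C-negative cells, all 35 measured genes of the 2C-like list were higher, with a median log2 fold change of 5.67. Zscan4c (ENSMUSG00000054272, chromosome 7, 11005745 to 11010547 in mm10), a zinc finger gene of the 2-cell embryo, averaged 5899 CPM (SD 3670, n = 2) against 126 CPM, a log2 fold change of 5.55 (SE 0.50, adjusted p = 3.36e-05). Zscan4d changed by 5.77 (SE 0.47, adjusted p = 1.63e-05). Zscan4 genes have near-identical copies, and reads that map to several places were kept apart from the gene counts, so the level of any single copy is uncertain. Zfp352 (chromosome 4, 90218820 to 90225702), a retrotransposon-derived zinc finger gene, averaged 1672 CPM (SD 977) against 21.1 and changed by 6.31 (SE 0.41, adjusted p = 5.49e-06), and Tcstv3 (chromosome 13, 120316878 to 120318178) by 7.41 (SE 0.67, adjusted p = 3.32e-05). The endogenous Dux-family gene Duxf3 (ENSMUSG00000075046, chromosome 10, 58229979 to 58232675) averaged 277 CPM (SD 148) against 2.55 and changed by 6.75 (SE 0.46, adjusted p = 6.17e-06). The interferon-related nuclear body gene Sp110 changed by 6.45 (SE 0.33, adjusted p = 2.47e-06) and Ubtfl1 by 5.67 (SE 0.30). The list passed as a set (adjusted p = 6.12e-31 with the preset correlation, 0.539 with an estimated correlation), and 35 members passed when adjusted over the list alone. All 35 were also higher with scaling by library totals.

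In the same D2 comparison, the heat shock chaperone gene Hspa1a (chromosome 17, 34969190 to 34972156) averaged 149 CPM (SD 70.1, n = 2) in 2C-positive cells against 2.57 and changed by 5.84 (SE 0.37, adjusted p = 4.81e-06), and Hspa1b changed by 4.90 (SE 0.32, adjusted p = 5.69e-06). Of 15 genes of the heat shock and early-response list, 9 were higher, 0 lower and 6 did not pass, the same count as when adjusted over the list alone. As a set the list had an adjusted p of 0.000677 (0.676 with an estimated correlation). Of 21 p53 targets, 3 were higher and 0 lower, also when adjusted over the list alone, including the death gene Pmaip1 at 2.12 (SE 0.17, adjusted p = 1.61e-05) and Plk2 at 2.19 (SE 0.26, adjusted p = 0.000247). The set did not pass (adjusted p = 0.529). Of 19 targets of nonsense-mediated decay, 6 were higher and 0 lower, also when adjusted over the list alone, among them the stress gene Gadd45b at 2.51 (SE 0.29, adjusted p = 0.000185). That set did not pass either (adjusted p = 0.142). With library totals, heat shock and early-response genes had 6 higher and 2 lower, p53 targets 3 and 3, and decay targets 3 and 5.

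Pluripotency genes moved both ways on D2. Of 28, 3 were higher, 13 lower and 12 did not pass in D2 2C-positive cells, against 4 higher and 15 lower when adjusted over the list alone, with a median log2 fold change of −0.61 and a set adjusted p of 0.0542. Fbxo15 was higher by 2.38 (SE 0.30, adjusted p = 0.000396) and Dppa2, a regulator of Dux, by 1.28 (SE 0.18, adjusted p = 0.000843). The core factor Sox2 (chromosome 3, 34650405 to 34652461) averaged 194 CPM (SD 84.3, n = 2) against 377 and was lower by −0.95 (SE 0.24, adjusted p = 0.0221), a call lost without D2 2C-negative replicate 1 (adjusted p = 0.122) or 2 (0.0764). Zfp42 was lower by −0.78 (SE 0.18, adjusted p = 0.0145), also lost without either of those libraries (0.0795 and 0.0835). Nanog did not pass at −0.60 (SE 0.20, adjusted p = 0.0555) and passed without D2 2C-positive replicate 1 (−0.32, adjusted p = 0.0477) or 2 (−0.96, adjusted p = 2.3e-09), with library totals (−1.12, 0.0237), without a filter (0.0236), in the unstranded column (0.0407) and with DESeq2 (−0.54, 0.0193). Pou5f1, the other core factor, did not pass at 0.04 (SE 0.19, adjusted p = 0.912). With scaling by library totals, which moved the median of all genes from −0.06 to −0.62, Pou5f1 was −0.59 (adjusted p = 0.0166), close to that median, and 2 pluripotency genes were higher and 18 lower. Klf4 did not pass at −0.16 (adjusted p = 0.467) and was −0.33 (adjusted p = 0.0383) without D2 2C-positive replicate 2.

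Lineage lists did not pass as sets between the D2 groups. Of 14 formative and primed genes, 2 were higher (Sox3 by 2.83, SE 0.38, and Igfbp3 by 2.61) and 5 lower, or 2 and 7 when adjusted over the list alone (set adjusted p = 0.222). Of 13 primitive endoderm genes, 2 were higher and 2 lower, including the laminin gene Lama1 at −1.31 (adjusted p = 0.00502), or 2 and 3 when adjusted over the list alone (set adjusted p = 0.529). Of 10 germ layer genes, 0 were higher and 3 lower, also when adjusted over the list alone (set adjusted p = 0.222), and of 12 trophectoderm genes 1 was lower, or 0 when adjusted over the list alone (set adjusted p = 0.736). That gene was Cdx2, at least 5.24-fold lower with 0 counts in D2 2C-positive cells, a call lost without D2 2C-negative replicate 1 (adjusted p = 0.138) or 2 (0.125) and among nuclear protein-coding genes alone (0.0533). Of 8 fibroblast genes, 3 were higher, also when adjusted over the list alone, with the collagen gene Col1a1 at 3.22 (adjusted p = 0.00144; set adjusted p = 0.0863).

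Lists of cell machinery did not pass as sets between the D2 groups, at adjusted p of 0.298 or more. Of 22 nonsense-mediated decay factors, 2 were higher, including Eif4a3 of the exon junction complex at 1.36 (SE 0.23, adjusted p = 0.00271), also when adjusted over the list alone, and the list's median of −0.02 and mean of 0.10 had opposite signs (set adjusted p = 0.736). Upf1 did not pass at −0.12 (adjusted p = 0.532), and was −0.68 (adjusted p = 0.045) with library totals. Of 25 genes of the Myc target list, which holds Myc and Mycn themselves, 2 were higher and 3 lower, also when adjusted over the list alone (set adjusted p = 0.798). Both Myc and Mycn were among the lower genes. Myc itself was lower by −0.80 (SE 0.23, adjusted p = 0.0365), a call lost without D2 2C-negative replicate 1 (0.154) or 2 (0.119). Of 12 DNA methylation genes, 2 were higher and 2 lower, or 2 and 5 when adjusted over the list alone (set adjusted p = 0.298), and of 22 chromatin repressors of the 2C state 2 were higher and 2 lower, also when adjusted over the list alone (set adjusted p = 0.421). The maintenance methyltransferase gene Dnmt1 did not pass at −0.41 (adjusted p = 0.0629) and was −0.53 (adjusted p = 0.000426) without D2 2C-positive replicate 2, and it also passed with library totals (−0.96, 0.0159), in the unstranded column (−0.46, 0.0406) and with DESeq2 (−0.34, 0.0146). Glycolysis had 4 of 17 higher and 1 lower, or 7 and 2 when adjusted over the list alone, and the G2 and M phase list had 5 of 20 higher, or 6 when adjusted over the list alone. Of 10 mitochondrial transcripts, 3 of which had 0 counts in both groups, and 12 housekeeping genes, 1 and 3 were higher, also when adjusted over the list alone. The balance of calls within these lists depended on the scaling, since with library totals Myc targets had 0 higher and 16 lower, G2 and M phase genes 0 and 11, chromatin repressors 0 and 9, DNA methylation 0 and 8, and glycolysis 0 and 5.

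Across all 16930 genes tested, 2430 were higher and 1256 lower in D2 2C-positive than in D2 2C-negative cells, so 65.9% of calls were higher. With library totals the counts were 1753 higher and 4738 lower, or 27.0% higher, so the balance of directions rested on the scaling. Among named genes with large increases were Clpsl2, at 8.76 (SE 1.00, adjusted p = 0.000183), the protease gene Tmprss9, at 8.52 (SE 0.81), and Tcstv1, at 8.06 (SE 0.71), which has close copies. BB287469 was at least 65.7-fold higher. Among named genes with decreases were Unkl at −2.64 (SE 0.44, adjusted p = 0.00245), the vitamin E transfer gene Ttpa at −2.09 (SE 0.32, adjusted p = 0.00127) and Spn at −1.93 (SE 0.27, adjusted p = 0.000782). Fitted to only the 4 libraries compared, edgeR called 670 genes higher and 0 lower, with 2777 genes at an unadjusted p under 0.05, while DESeq2 on all libraries called 2979 higher and 1527 lower. The fit of 4 libraries ended calls such as those of Unkl (adjusted p = 0.148), Ttpa (0.111), Spn (0.0747), Fbxo15 (0.0696), Dppa2 (0.0683), Sox2 (0.259), Zfp42 (0.229) and Myc (0.175), and kept those of Zscan4c, Zfp352, Duxf3 and Hspa1a. Counts were 1301 and 224 without D2 2C-negative replicate 1, 1290 and 231 without replicate 2, 3039 and 2263 without D2 2C-positive replicate 1, and 4611 and 5124 without replicate 2.

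On the scale of the gene tables, most repeat subfamilies were higher in D2 2C-positive than in D2 2C-negative cells. The endogenous retrovirus MERVL-int, whose RNA marks the 2-cell embryo, averaged 35660 CPM (SD 11200, n = 2) against 791 (SD 115), a log2 fold change of 5.50 (SE 0.67, adjusted p = 9.12e-16). Its promoter repeat MT2_Mm averaged 10860 CPM (SD 5850) against 177 and changed by 5.94 (SE 0.62, adjusted p = 2.86e-20). The p-values of repeats cannot be set against those of genes. Of 933 subfamilies, 823 were higher and 2 lower, with a median of 3.15. Repeat counts per 100 gene counts were 66.8 and 35.1 in the D2 2C-positive libraries and 5.54 and 6.71 in D2 2C-negative. On the gene scale, such a broad shift of reads outside exons cannot be told apart from a rise of single subfamilies. When repeats were scaled on their own counts the median was −0.03 and 248 were higher and 255 lower, while MERVL-int stayed higher at 2.36 (adjusted p = 2.15e-06) and MT2_Mm at 2.70. On the gene scale, 10 of 11 class I and II retroviruses (median 4.39, set adjusted p = 0.17), all 13 other ERVL and MaLR repeats (4.22, 0.0659), all 6 LINE1 (3.77, 0.194), both satellites (5.65) and all 7 SINE subfamilies (4.08, 0.194) were higher. Large increases were in tRNA-Ala-GCY (at least 36.4-fold), tRNA-Pro-CCA (252-fold, 95% interval 45.2 to 9950), tRNA-Leu-TTG (218-fold, 39.2 to 8620) and tRNA-Ile-ATA (7.20, SE 0.99), of which the first 2 had 0 counts in D2 2C-positive replicate 2. The tRNA-Ala-GCY call was lost with DESeq2 (adjusted p = 0.0826), and it was not among the repeats tested on their own scale. MER126 was at least 4.05-fold lower and MLT1F2-int lower by −1.77, a call lost without D2 2C-positive replicate 2 (adjusted p = 0.0732). Subfamilies called lower were 8 without D2 2C-positive replicate 1 and 6 without replicate 2.

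**Figure D2:**
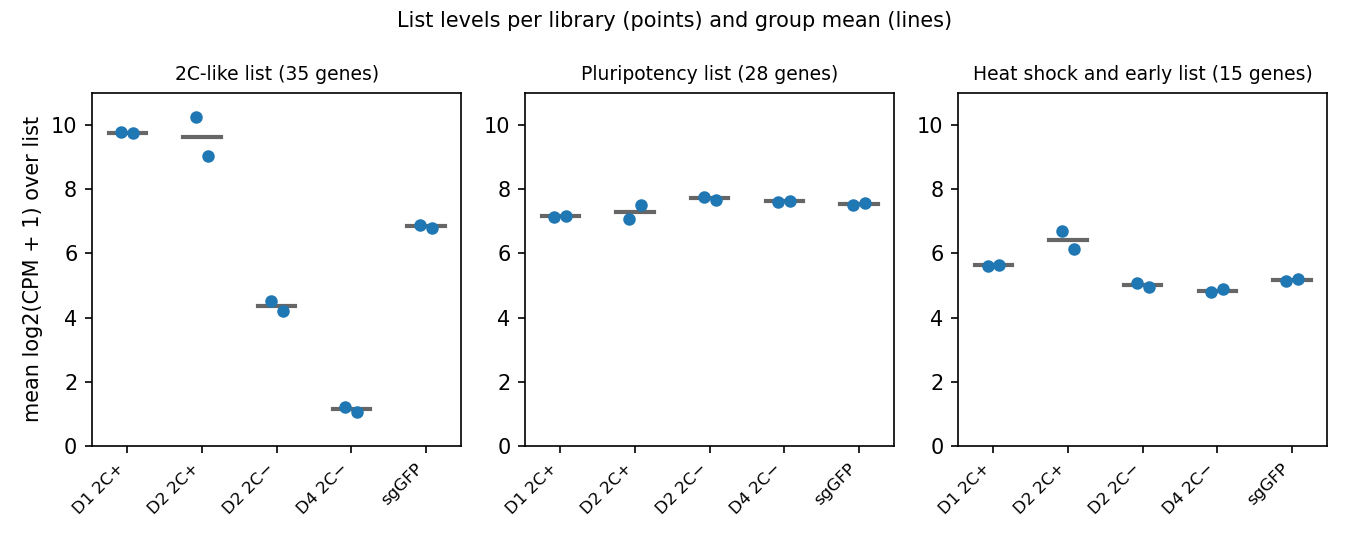
Mean log2(CPM + 1) over the 35 2C-like, 28 pluripotency and 15 heat shock and early-response genes (1 panel each), with a point per library and a line at each group mean. The 2C-like list averaged 9.75 in D1 2C-positive, 9.63 in D2 2C-positive, 4.36 in D2 2C-negative, 1.15 in D4 2C-negative and 6.85 in sgGFP libraries.

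Between D2 and D1 2C-positive cells, the 2C-like list did not pass as a set (adjusted p = 0.669), and its median of −0.16 and mean of 0.01 had opposite signs. Of its 35 genes 1 was higher, also when adjusted over the list alone: Duxf3, at 277 CPM (SD 148, n = 2) against 86.1 (SD 2.15), changed by 1.68 (SE 0.36, adjusted p = 0.0482). Zscan4c did not pass at −0.37 (SE 0.41, adjusted p = 0.63). Zscan4d at −0.24 and Zfp352 at −0.39 did not pass, but without D2 2C-positive replicate 1 they were −1.03 (adjusted p = 0.0182) and −1.17 (adjusted p = 1.75e-10). Tcstv3 did not pass at 0.60, and was 1.28 (adjusted p = 0.00121) without replicate 2. Gadd45a (chromosome 6, 67035096 to 67037457), a growth arrest and decay target gene, averaged 53.4 CPM against 12.7 and was higher by 2.07 (SE 0.18, adjusted p = 0.00824). Gadd45b was higher by 3.06 (SE 0.32, adjusted p = 0.0122) and Gadd45g by 4.30 (SE 0.59, adjusted p = 0.0299). The p53 targets Bbc3 and Cdkn1a were higher by 1.93 (SE 0.31) and 1.20 (SE 0.22), each at an adjusted p of 0.0383, and Hspa1a was higher by 2.09 (SE 0.32, adjusted p = 0.0368). Every gene call of this comparison was lost without D1 2C-positive replicate 1 or replicate 2, where edgeR called 0 genes with 2110 and 2480 at an unadjusted p under 0.05. Gadd45a then had adjusted p of 0.354 and 0.185.

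As sets, 4 gene lists passed between D2 and D1 2C-positive cells. Nonsense-mediated decay targets had 3 of 19 higher, or 6 when adjusted over the list alone, with a median of 0.34 (adjusted p = 0.000557, 0.385 with an estimated correlation). The p53 targets had 3 of 21 higher, or 6 when adjusted over the list alone, with a median of 0.39 (adjusted p = 0.000373, 0.28 with an estimated correlation). The mean log2(CPM + 1) of the p53 list was 5.07 in D1 and 5.57 in D2 2C-positive libraries. It was 5.43 in D2 2C-negative, 5.37 in D4 2C-negative and 5.46 in sgGFP libraries, so D1 stood lowest. Heat shock and early-response genes had 5 of 15 higher, or 8 higher and 1 lower when adjusted over the list alone (median 0.88, adjusted p = 0.00122, 0.585 with an estimated correlation). Mitochondrial transcripts were lower in 5 of 10, or 7 when adjusted over the list alone (median −1.37, adjusted p = 0.00018, 0.385 with an estimated correlation). Of the 10, mt-Co2, mt-Co3 and mt-Atp6 had 0 counts in both groups, and without them the median was −1.65 (adjusted p = 8.97e-07, 0.331 with an estimated correlation). The respiratory chain transcript mt-Nd4 averaged 1045 CPM (SD 61.0, n = 2) on D2 against 4355 (SD 513) on D1 and was lower by −2.06 (SE 0.22, adjusted p = 0.0122). With library totals, 0 p53 targets and 3 heat shock and early-response genes were higher and 3 mitochondrial transcripts lower. Mitochondrial reads can also map to nuclear copies. Mitochondrial genes took 2.24% and 2.04% of counts in the D2 and 4.511% and 4.003% in the D1 libraries. They took 1.83% and 1.71% in D2 2C-negative and 2.44% and 1.82% in D4 2C-negative libraries. In sgGFP they took 3.17% and 3.22%, so D1 2C-positive was the highest group and D2 2C-positive lay near the 2C-negative groups.

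The other lists did not pass as sets between D2 and D1 2C-positive cells. Pluripotency genes had 1 of 28 higher, or 4 higher and 2 lower when adjusted over the list alone (adjusted p = 0.202), namely Klf4 at 0.80 (SE 0.16, adjusted p = 0.0429, and 0.354 and 0.251 without D1 2C-positive replicates 1 and 2). Pou5f1 at 0.23, Nanog at −0.13, Zfp42 at 0.22, Sox2 at 0.78 (adjusted p = 0.108), Myc at 0.82 (adjusted p = 0.102), Upf1 at 0.28 and Dnmt1 at −0.13 did not pass. Without D2 2C-positive replicate 1, Sox2 (1.16, adjusted p = 2.21e-11), Myc (0.97, adjusted p = 0.000437), Zfp42 (0.46, adjusted p = 0.00327) and Upf1 (0.38, adjusted p = 0.0185) passed. Without replicate 2, Pou5f1 (0.45, adjusted p = 0.00536), Nanog (−0.51, adjusted p = 0.00225) and Myc (0.64, adjusted p = 0.0482) passed. DNA methylation had 1 gene higher (Gadd45a, also a decay target), or 2 higher and 3 lower when adjusted over the list alone (adjusted p = 0.739). Decay factors and glycolysis had 1 gene lower each, also when adjusted over the list alone (0.872 and 0.0929). No gene of the remaining lists passed over all genes, while adjusted over the list alone formative genes had 2 higher and 2 lower, chromatin repressors and G2 and M phase genes 4 lower each, primitive endoderm 1 higher and 1 lower, and trophectoderm 3 higher. Their adjusted p were 0.765, 0.178, 0.0929, 0.853 and 0.0929. Myc targets (0.17), germ layer (0.669), fibroblast (0.436) and housekeeping genes (0.0929) had 0 either way. Median and mean had opposite signs for the formative (0.16 and −0.24), DNA methylation (−0.15 and 0.12) and primitive endoderm lists (−0.10 and 0.11).

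Across all genes, 146 were higher and 197 lower in D2 than in D1 2C-positive cells. Largest among the named increases after Gadd45g was Agap2 at 4.03 (SE 0.70, adjusted p = 0.0383), which was −0.55 (adjusted p = 0.154) in the unstranded column. Ttpa was lower by −2.73 (SE 0.33, adjusted p = 0.0264) and the Nodal inhibitor gene Lefty1 by −2.28 (SE 0.45, adjusted p = 0.0429). The Lefty1 call was also lost without D2 2C-positive replicate 1 (0.106) or 2 (0.162). Library totals, which moved the median of all genes from 0.02 to 0.24, gave 44 higher and 5 lower, or 89.8% higher against 42.6%. DESeq2 called 662 and 840, and edgeR on the 4 libraries alone called 0 with 1156 genes at an unadjusted p under 0.05. Without D2 2C-positive replicate 1 the counts were 2956 and 2972, and without replicate 2 they were 2126 and 3104.

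Between D2 and D1 2C-positive cells, 15 of 933 repeat subfamilies were higher and 2 lower. MERVL-int at −0.27 (SE 0.55, adjusted p = 0.937) and MT2_Mm at −0.06 (SE 0.50, adjusted p = 0.984) did not pass, but without D2 2C-positive replicate 1 they were −0.64 (adjusted p = 0.0199) and −0.76 (adjusted p = 0.00629). The simple repeat _CATTC_n was higher by 6.32 (SE 0.59, adjusted p = 7.18e-24) and tRNA-Leu-TTG at least 12.7-fold. Kanga1a was lower by −2.55 (SE 0.62, adjusted p = 0.00518). LTR84a at 3.48 (SE 1.00), tRNA-Glu-GAA at 3.69 (SE 0.95) and MER95 at −1.77 (SE 0.52) also passed, but tRNA-Glu-GAA was 0.54 without D2 2C-positive replicate 1. Without D1 2C-positive replicates 1 and 2, only 1 and 3 subfamilies were higher and the calls of Kanga1a (0.301 and 0.139), tRNA-Leu-TTG (0.435 and 0.337), tRNA-Glu-GAA (0.435 and 0.303), LTR84a (0.435 and 0.577) and MER95 (1 and 0.235) were lost. Without D2 2C-positive replicate 1 there were 9 higher and 288 lower, and without replicate 2 there were 284 higher and 24 lower. SINE subfamilies passed as a set (median 1.25, adjusted p = 0.00343, 0.838 with an estimated correlation), with 0 of 7 passing over all repeats and 5 higher when adjusted over the list alone. The rise lay in D2 2C-positive replicate 1, where the list's mean log2(CPM + 1) was 14.86. It was 13.1 in replicate 2, against 13.01 and 13.22 in the D1 libraries. One of the 2 satellites was higher, or both when adjusted over the list alone. GSAT_MM was at 6254 CPM in D2 2C-positive replicate 1 but 1857 in replicate 2, against 2077 and 2114 on D1. SYNREP_MM was at 90.52 and 26.12 CPM on D2, against 15.4 and 11.91 on D1. The other ERVL and MaLR (median 0.35, adjusted p = 0.247), LINE1 (median −0.07, mean 0.01, 0.562) and class I and II lists (median 0.06, mean −0.06, 0.562) did not pass.

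In D4 against D2 2C-negative cells, 30 of the 35 2C-like genes were lower, or 34 when adjusted over the list alone, and the median was −4.84 (−4.76 with genes at 0 set to their bound). Zscan4c averaged 4.80 CPM against 126 and was lower by −4.73 (SE 0.50, n = 2, adjusted p = 0.000579). Zscan4d was lower by −4.95 (SE 0.46), Zfp352 by −4.87 (SE 0.46), each at an adjusted p of 0.000297, and Tdpoz3, which has near-identical copies, by −5.83 (SE 0.35, adjusted p = 7.27e-05). Duxf3 was lower by −4.50 (SE 0.74, adjusted p = 0.00908), a call lost without D4 2C-negative replicate 1 (0.129) or 2 (0.115), and Tcstv3 by −5.29 (SE 0.74, adjusted p = 0.00339), likewise lost (0.0829 and 0.0888). Tcstv1, Tdpoz1, BB287469, Pramel6 and Pramel7 did not pass. As a set the list had an adjusted p of 5.98e-54 (0.33 with an estimated correlation). No label names a batch, though the D4 libraries carry other kinds of label than the D2 libraries. Their records also form another block of the series. In every comparison of D4 with D2, a change between days therefore cannot be told apart from a batch.

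In the fit of all 10 libraries, pluripotency genes did not differ detectably between D4 and D2 2C-negative cells, with 0 of 28 passing, also when adjusted over the list alone (median −0.02, adjusted p = 0.787). Pou5f1 was −0.15 (SE 0.19, adjusted p = 0.764), Nanog −0.18, Sox2 0.17, Klf4 0.06 and Zfp42 0.34. Zfp42 passed with only the 4 libraries compared (0.33, adjusted p = 0.0315) and without D2 2C-positive replicate 1, a library of neither group (0.35). The Nodal inhibitor gene Lefty2 (chromosome 1, 180893108 to 180899103) was higher by 2.20 (SE 0.27, adjusted p = 0.0016), as were the immediate-early gene Egr1 by 1.79 (SE 0.23, adjusted p = 0.00195), the desaturase gene Scd2 by 1.49 (SE 0.17, adjusted p = 0.000837) and the phosphofructokinase gene Pfkp by 1.13 (SE 0.12, adjusted p = 0.000675). Lefty1 was higher by 2.08 (SE 0.39, adjusted p = 0.0208), which was lost without D2 2C-negative replicate 2 (0.118) or D4 2C-negative replicate 1 (0.0886) or 2 (0.178). Glycolysis passed as a set (median 0.32, adjusted p = 0.0414, 0.658 with an estimated correlation), with 1 of 17 higher, or 2 when adjusted over the list alone. Sox3 was lower by −2.61 (adjusted p = 0.00906), a call lost without D2 2C-negative replicate 1 (0.0558) or D4 2C-negative replicate 1 (0.12).

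The other lists did not pass as sets between D4 and D2 2C-negative cells. Formative genes and decay targets had 2 lower each, and germ layer, DNA methylation and housekeeping genes 1 lower each, the same when adjusted over the list alone (set adjusted p = 0.128, 0.822, 0.0646, 0.822 and 0.542). Gadd45a (−0.70, adjusted p = 0.0496) was both a decay target and the DNA methylation gene. Settings that ended its call included RLE size factors (0.0521), library totals (0.189), the unstranded column (0.225), the replicate block (0.07) and thinning (0.0645). The call of Actb, the housekeeping gene, was lost with RLE size factors (0.0846), the replicate block (0.0692) and thinning (0.0919). That of the germ layer gene Pax6 was lost with library totals (0.108). Heat shock and early-response genes had 1 higher and 1 lower, or 1 and 2 when adjusted over the list alone (0.475). Primitive endoderm (0.787) and trophectoderm (0.128) had 0, or 1 lower when adjusted over the list alone. Decay factors, Myc targets and p53 targets (0.822 each), chromatin repressors and fibroblast genes (0.475 each), G2 and M phase genes (0.319) and mitochondrial transcripts (0.188) had 0 either way. Upf1 at −0.30, Myc at −0.20 and Dnmt1 at −0.00 did not pass, and Upf1 passed without D2 2C-positive replicate 1 (−0.29, adjusted p = 0.026).

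Over all genes, 55 were higher and 384 lower in D4 than in D2 2C-negative cells, so 12.5% of calls were higher. Pramef6 was lower by −6.14 (SE 0.60, adjusted p = 0.000369). Olfr787 was at least 13.0-fold lower and Ecm2 at least 9.95-fold lower with 0 counts on D4, calls lost without D4 2C-negative replicate 2 (0.0566 and 0.0848). DESeq2 called 275 higher and 673 lower, or 29.0% higher. Counts were 10 and 243 without D2 2C-negative replicate 1, 11 and 265 without replicate 2, 9 and 187 without D4 2C-negative replicate 1, 17 and 139 without replicate 2, and 2073 and 2289 without D2 2C-positive replicate 1.

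Of 933 repeat subfamilies, edgeR called 0 higher and 48 lower in D4 than in D2 2C-negative cells, with 130 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 41 lower. MERVL-int averaged 229 CPM (SD 29.5, n = 2) against 791 and was lower by −1.79 (SE 0.57, adjusted p = 0.0381), and MT2_Mm was lower by −2.10 (SE 0.53, adjusted p = 0.00309). The MERVL-int call was lost without D2 2C-negative replicates 1 (0.149) or 2 (0.346) or D4 2C-negative replicates 1 (0.382) or 2 (0.64). The MT2_Mm call was lost without D2 2C-negative replicate 2 (0.0777) or D4 2C-negative replicates 1 (0.178) or 2 (0.278). Both satellites were lower, the major satellite GSAT_MM by −2.59 (adjusted p = 2.64e-05) and SYNREP_MM by −1.89 (adjusted p = 0.00468). Of the 4 libraries, GSAT_MM was highest in D2 2C-negative replicate 1 (63.9 CPM) and was −1.52 (adjusted p = 0.174) without replicate 1. Its call was also lost without D4 2C-negative replicate 2 (0.0897) or D2 2C-positive replicate 1 (0.0642), and with repeats scaled on their own counts (0.0634). The SYNREP_MM call was lost without D2 2C-negative replicate 1 (0.158) or D4 2C-negative replicates 1 (0.173) or 2 (0.183). HY1, a small RNA repeat, was at least 10.2-fold lower, and ERVB4_3-LTR_MM was lower 63.9-fold (95% interval 11.5 to 2520). MER92C and Eulor8 were at least 4.15-fold and 4.42-fold lower, but Eulor8 was 0.00 without D2 2C-negative replicate 2, and the MER92C call was lost without any of the 4 libraries (adjusted p 0.0838 to 0.608). Class I and II retroviruses (median −0.27, tested upward against the other repeats, adjusted p = 0.208), LINE1 (0.06, mean −0.02, 0.208), other ERVL and MaLR (−0.41, 0.875) and SINE (−0.43, 0.875) had 0 called. Counts lower were 31 and 19 without D2 2C-negative replicates 1 and 2, 17 and 9 without D4 2C-negative replicates 1 and 2, and 201 without D2 2C-positive replicate 1, where 20 were higher.

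In sgGFP against D4 2C-negative cells, 33 of the 35 2C-like genes were higher, also when adjusted over the list alone, with a median of 7.79 (7.57 with genes at 0 set to their bound). Zscan4c averaged 1390 CPM against 4.80 and was higher by 8.19 (SE 0.58, n = 2, adjusted p = 1.3e-05). Zscan4d was higher by 8.44 (SE 0.54), Zfp352 by 7.57 (SE 0.48), each at an adjusted p of 7.48e-06, Tcstv3 by 8.63 (SE 0.78) and Duxf3 by 6.28 (SE 0.66, adjusted p = 0.00018). Obox3 was at least 64.3-fold and Tcstv1 at least 172-fold higher. The Tdpoz3 gene rose by 8.13 and Gm5662 by 7.30 (SE 0.34, adjusted p = 2.57e-06). Pramel6 and Pramel7 did not pass. The set had an adjusted p of 5.34e-45 (0.353 with an estimated correlation). With library totals 33 were also higher. The p53 target Pmaip1 was higher by 2.17 (SE 0.17, adjusted p = 2.74e-05) and Hspa1a by 3.81 (SE 0.42, adjusted p = 0.000269).

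The Wnt effector Lef1 (chromosome 3, 131110471 to 131224356) averaged 0.826 CPM in sgGFP cells against 9.06 in D4 2C-negative cells and was lower by −3.44 (SE 0.57, adjusted p = 0.00409), a call lost without D4 2C-negative replicate 2 (0.0508) or sgGFP replicate 1 (0.0787). Dppa3 (chromosome 6, 122626410 to 122630272), a germline and maternal factor, was lower by −2.58 (SE 0.28, adjusted p = 0.000241), the splicing regulator Esrp1 by −2.23 (SE 0.31, adjusted p = 0.00136) and Egr1 by −1.97 (adjusted p = 0.000385). The DNA methylation genes Dnmt3l and Dnmt3b were lower by −1.31 (SE 0.18, adjusted p = 0.00128) and −1.17 (SE 0.16, adjusted p = 0.00137), and the naive factor Klf2 by −1.07 (SE 0.13, adjusted p = 0.000631). Of 28 pluripotency genes, 3 were higher and 3 lower, or 4 and 4 when adjusted over the list alone (set adjusted p = 0.145). Pou5f1 at 0.03 (adjusted p = 0.96), Nanog at 0.36, Sox2 at −0.54, Klf4 at 0.37 and Zfp42 at 0.12 did not pass, nor did Myc at −0.50, Upf1 at −0.29 and Dnmt1 at −0.18. Fitted by edgeR to only the 4 libraries compared, Nanog (adjusted p = 0.0334), Sox2 (1.28e-05), Klf4 (0.0298), Myc (0.00095) and Upf1 (0.0128) passed. Without D2 2C-positive replicate 1, a library of neither group, Nanog (adjusted p = 0.00276), Sox2 (1.62e-05), Klf4 (0.00266), Myc (0.00436) and Upf1 (0.0259) passed.

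Myc targets passed as a set in sgGFP against D4 2C-negative cells, with 4 of 25 lower, or 1 higher and 4 lower when adjusted over the list alone (median −0.21, adjusted p = 0.00631, 0.556 with an estimated correlation). The lower genes included Mycn itself, a member of that list. Mycn was lower by −1.33 (adjusted p = 0.00983), lost without D4 2C-negative replicate 1 (0.0713) or 2 (0.0916) or sgGFP replicate 1 (0.129). Mitochondrial transcripts passed as a set with 6 of 10 higher, or 9 when adjusted over the list alone (median 0.83, adjusted p = 9.16e-06, 0.353 with an estimated correlation). Of these, mt-Atp6, mt-Co2 and mt-Co3 had 0 counts in the 8 libraries outside sgGFP, so a difference in how the tables were made cannot be told apart from a difference in RNA. The mt-Atp6 call, at least 25.1-fold higher, was lost without any of the 4 libraries compared (adjusted p 0.116 to 0.294). Among the other 7 transcripts, 3 were higher, or 6 when adjusted over the list alone (median 0.66, adjusted p = 0.00746, 0.522 with an estimated correlation). With library totals 0 mitochondrial transcripts were higher and 2 Myc targets lower. Formative genes had 3 higher and 4 lower, or 3 and 6 when adjusted over the list alone (set adjusted p = 0.0785), with Igfbp3 higher by 2.64 (adjusted p = 0.000546). DNA methylation had 1 higher and 2 lower (0.122), chromatin repressors 2 lower (0.0942), p53 targets 2 higher and 1 lower (0.492), germ layer genes 2 lower (0.291) and heat shock and early-response genes 4 higher and 1 lower (0.486), the same when adjusted over the list alone. Glycolysis had 3 higher and 1 lower, or 6 and 2 when adjusted over the list alone (0.772), with Pfkp lower by −0.98 (adjusted p = 0.000647). Primitive endoderm had 1 higher, or 3 when adjusted over the list alone (0.291), decay factors 1 higher, or 0 (0.128), fibroblast genes 1 higher, or 1 higher and 1 lower (0.42), and housekeeping genes 0, or 2 higher (0.42). Decay targets (0.42), G2 and M phase (0.0775) and trophectoderm genes (0.122) had 0 either way. Median and mean had opposite signs for decay targets (−0.04 and 0.03), p53 targets (−0.01 and 0.09), germ layer (−0.14 and 0.01) and fibroblast genes (0.63 and −0.11).

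Over all genes, 1194 were higher and 337 lower in sgGFP than in D4 2C-negative cells, so 78.0% of calls were higher. Some genes, mt-Co2 among them, had counts in sgGFP only. For part of these calls, a difference in how the gene tables were made therefore cannot be told apart from a difference in RNA. Library totals moved the median of all genes from 0.10 to −0.01 and gave 909 higher and 199 lower, and DESeq2 called 1506 and 788, or 65.6% higher. Counts were 537 and 87 without D4 2C-negative replicate 1, 482 and 74 without replicate 2, 593 and 47 without sgGFP replicate 1, 637 and 76 without replicate 2, and 4064 and 2103 without D2 2C-positive replicate 1.

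Of 933 repeat subfamilies, 694 were higher and 1 lower in sgGFP than in D4 2C-negative cells, with a median of 1.61. Scaled on their own counts, 193 were higher and 135 lower with a median of −0.01. MERVL-int averaged 6867 CPM (SD 167, n = 2) against 229 and was higher by 4.91 (SE 0.65, adjusted p = 1.71e-12), or 3.31 on the repeats' own scale, and MT2_Mm was higher by 4.32 (SE 0.58, adjusted p = 3.32e-12), or 2.71. HY1 was at least 32.6-fold, RLTR46 at least 19.6-fold and MER95 at least 17.5-fold higher, and ERVB4_3-LTR_MM was 279-fold higher (95% interval 50.1 to 11000). MER102b was lower by −1.89 (SE 0.41, adjusted p = 1.42e-05). On the gene scale, 8 of 11 class I and II retroviruses (median 2.37, set adjusted p = 0.0813), all 13 other ERVL and MaLR repeats (1.97, 0.0813), all 6 LINE1 (1.90, 0.379), both satellites (3.67) and all 7 SINE subfamilies (1.62, 0.379) were higher. Higher counts fell to 473 without D4 2C-negative replicate 2, with 587, 534 and 593 without D4 2C-negative replicate 1 and sgGFP replicates 1 and 2.

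Levels of the SynDux transgene and of a TdTomato transcript, both chosen after their values were seen, were lowest in D4 2C-negative libraries. SynDux averaged 1430 CPM (SD 15.1, n = 2) in D1 2C-positive, 1618 (SD 613) in D2 2C-positive, 34.5 (SD 3.80) in D2 2C-negative, 0.0366 in D4 2C-negative and 132 (SD 1.70) in sgGFP libraries. It was higher by 5.55 (SE 0.31, adjusted p = 2.64e-06) in D2 2C-positive than in D2 2C-negative cells and did not differ detectably from D1 2C-positive cells (0.18, adjusted p = 0.716), though without D2 2C-positive replicate 2 it was 0.51 (adjusted p = 0.0013). With 2 counts on D4, it was lower 813-fold (95% interval 225 to 6720) than in D2 2C-negative and higher in sgGFP by 3120-fold (862 to 25700). TdTomato averaged 5024 CPM (SD 2950) in D2 2C-positive and 14.7 (SD 13.1) in D2 2C-negative cells, a change of 8.42 (SE 0.76, adjusted p = 3.21e-05), and 118 (SD 5.73) in sgGFP against 0.502 in D4 2C-negative cells. It was lower by −4.83 in D4 than in D2 2C-negative cells (adjusted p = 0.00884). This call was lost with only the 4 libraries compared (−4.85, adjusted p = 0.215), and without D4 2C-negative replicate 1 or 2 or D2 2C-positive replicate 1.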

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

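The strand of the transgene reads was examined only after the counts were seen, and no tests were run on it. The strand column not used for gene levels held SynDux reads in D4 2C-negative libraries, above the 3 counts that a count of 0 allows. There were 112 opposite-strand counts in D4 2C-negative replicate 1 and 139 in replicate 2, or 5.66 and 5.09 CPM, where the sense strand had 0 and 2. They made up 100% and 98.6% of the stranded SynDux counts of those libraries. In the same column the other libraries had 1.49 to 30.7 CPM, the highest in D2 2C-positive replicate 1. TdTomato had 0 and 1 opposite-strand counts in the D4 2C-negative libraries. No explanation was tested.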

How the results depend on the processing

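Alternatives limited to list members with counts in both groups, to nuclear protein-coding genes, to libraries thinned to 5986009 counts, or to a fit without D2 2C-positive replicate 1 for comparisons it is not part of were tests chosen after the data were seen, and the others were chosen before. Where a library is left out, the lone sample is assumed to vary like the other groups, and the cause of a change was not tested unless stated. In D2 2C-positive against D2 2C-negative cells, genes called higher were 2430, and 670 (with 0 lower) with only the 4 libraries compared, which leaves fewer libraries to estimate the spread; the other alternatives stayed within 1.5 times, leaving out 1 library aside. Genes called lower, 1256 at first, were 4738 with library totals, 743 after thinning and 648 with the 2-fold minimum. For D2 against D1 2C-positive cells (146 higher, 197 lower), counts were 44 and 5 with library totals, 255 and 324 without a filter, 11 and 12 with the replicate block, 86 and 72 after thinning, 662 and 840 with DESeq2 and 0 and 0 with only 4 libraries, and 74 lower with the 2-fold minimum. For D4 against D2 2C-negative cells (55 higher, 384 lower), counts higher were 32 with library totals, and counts higher and lower were 33 and 217 with nuclear protein-coding genes, which are fewer genes, 27 and 209 after thinning, 275 and 673 with DESeq2 and 1523 and 1808 with only 4 libraries. For sgGFP against D4 2C-negative cells (1194 higher, 337 lower), 721 were higher among nuclear protein-coding genes, 199 lower with library totals, 788 lower with DESeq2, 194 lower with the 2-fold minimum, and 3587 higher and 2828 lower with only 4 libraries. Replicate block counts were otherwise close, at 2230 and 1101, 47 and 379, and 1101 and 301 in those 3 comparisons. Correlations between the replicate differences of the groups were −0.0348 to 0.105, the highest between D2 2C-negative and D2 2C-positive. These low values gave no clear sign of pairing by replicate number. They cannot show that the libraries were unpaired, since the D2 2C-positive replicates lay far apart.

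For repeats, scaling on their own counts, which by construction sets the typical subfamily near 0, gave 248 higher and 255 lower in D2 2C-positive against D2 2C-negative cells, 38 and 30 in D2 against D1 2C-positive, 32 higher in D4 against D2 2C-negative, and 193 and 135 in sgGFP against D4 2C-negative. With only 4 libraries 1 subfamily was lower in the first comparison, 7 were higher in the second, 4 higher and 90 lower in the third, and 3 lower in the last. In D2 against D1 2C-positive cells the replicate block gave 9 higher and 1 lower, and DESeq2 6 higher and 0 lower, with 91 at an unadjusted p under 0.05. DESeq2 gave 1 higher in D4 against D2 2C-negative cells.

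Leaving out 1 library gave ranges of 1290 to 4611 genes higher and 224 to 5124 lower in D2 2C-positive against D2 2C-negative cells, 0 to 2956 and 0 to 3104 in D2 against D1 2C-positive, 9 to 2073 and 139 to 2289 in D4 against D2 2C-negative, and 482 to 4064 and 47 to 2103 in sgGFP against D4 2C-negative. For repeats the ranges were 781 to 843 higher and 2 to 8 lower, 1 to 284 and 0 to 288, 0 to 20 and 9 to 201, and 473 to 779 and 1 to 2. The upper ends for genes came without a D2 2C-positive library, the pair that lay far apart.

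With an estimated correlation, 12 list tests were no longer past the threshold: 2C-like (0.539) and heat shock (0.676) in D2 2C-positive against D2 2C-negative cells; decay targets (0.385), p53 targets (0.28), mitochondrial (0.385), heat shock (0.585) and SINE (0.838) in D2 against D1 2C-positive; 2C-like (0.33) and glycolysis (0.658) in D4 against D2 2C-negative; 2C-like (0.353), Myc targets (0.556) and mitochondrial (0.353) in sgGFP against D4 2C-negative. All 88 list tests kept their side of the threshold with the replicate block, and all 72 of gene lists did with only the members that had counts in both groups. The named results that changed direction were Rrs1 (−0.01) and Pou5f1 (−0.59) in D2 2C-positive against D2 2C-negative cells with library totals, whose median was −0.62; Agap2 (−0.55) in D2 against D1 2C-positive cells with the unstranded column; and the repeat Eulor8 in D4 against D2 2C-negative cells, which ran from −6.27 to 0.00 with 1 library left out. Further calls of genes and repeats named in the text changed in settings other than the fit of 4 libraries and leaving out 1 library. In D2 against D1 2C-positive cells, the calls of Duxf3 (0.0509 to 0.092 in 5 settings), Klf4 (0.0509 to 0.115 in 3), Lefty1 (0.0568 to 0.0959 in 3), Cdkn1a and Bbc3 (0.0569 to 0.0882 in 2 each), Ttpa with library totals (0.058) and Hspa1a and Agap2 with the replicate block (0.0569 each) were lost, and with DESeq2 Sox2 (0.0254) and Myc (0.0401) passed. DESeq2 also ended those of tRNA-Glu-GAA, LTR84a, Kanga1a and MER95 (0.139 to 0.509), the repeats' own scale those of tRNA-Glu-GAA (0.125), Kanga1a (0.132) and MER95 (0.124), and the replicate block those of tRNA-Glu-GAA (0.0826), LTR84a (0.0573) and MER95 (0.067). In D4 against D2 2C-negative cells, Lefty1 (0.0674), Sox3 (0.0747), Olfr787 (0.12) and Duxf3 (0.15) were lost after thinning, Tcstv3 (0.103) and TdTomato (0.169) without a filter, and Eulor8 (0.164) and MER92C (0.067) with DESeq2, and on the repeats' own scale (0.258 and 0.08), with MER92C lost with the replicate block too (0.0695). In sgGFP against D4 2C-negative cells mt-Atp6 was lost with library totals (0.0511), and Upf1 passed with DESeq2 (0.0311). Thinning left 13902 genes to test, so genes under that filter have no value there. In simulated data of this size, where all groups shared the same spread trend, at most 49.3% of 2-fold changes were recovered. Changes of that size may therefore often be missed, though the shares need not hold for groups that differ in spread.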

Other observations

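The tests of gene families and the 3 patterns below were chosen after the result was seen, except the test for genomic DNA, which was set out before. Gene families with at least 10 members were compared with the 13907 tested genes left after predicted genes and pseudogenes were removed, by a one-sided Fisher's exact test, adjusted over 1352 tests. The test counts genes as if independent, which members of a family are not. Its p-values therefore do not measure the spread between libraries. In D2 2C-positive against D2 2C-negative cells, 46 of 52 histone genes were higher (median 4.29, adjusted p = 1.71e-34), 45 with library totals (median 3.59) and 44 of 61 without a filter. Hist1h2be averaged 7.66 CPM against 0.599, a change of 3.64 (SE 0.42, adjusted p = 0.000177). Histone genes called higher were 26 and 24 of 54 without D2 2C-negative replicates 1 and 2, and 40 and 50 without D2 2C-positive replicates 1 and 2. In sgGFP against D4 2C-negative cells 11 of 52 were higher (adjusted p = 0.014), but 4 of 39 after thinning, 0 to 2 without any 1 of the 4 libraries compared, and 36 without D2 2C-positive replicate 1. Of 1103 olfactory receptor genes 25 passed the filter, which keeps a near-silent gene only where some group has counts, so their enrichment is not given. Without a filter, 26 of the 174 with a count were higher in D2 2C-positive than in D2 2C-negative cells (14.9%, against 8.17% of all such genes). A near-silent gene enters that set only through the libraries where it has reads, so these shares cannot show enrichment either. Olfr376 stood at 202 CPM against 3.25 (log2 fold change 5.95, SE 0.47).

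Ribosomal protein genes of the large subunit were higher in D2 2C-positive than in D2 2C-negative cells in 22 of 50 (median 0.77, adjusted p = 1.51e-06), but 2 were higher and 1 lower with library totals (median 0.12), and counts were 1 and 0 without D2 2C-negative replicates 1 and 2, 15 of 52 (median 0.25) without D2 2C-positive replicate 1 and 46 (1.14) without replicate 2. Those of the small subunit were higher in 18 of 43 (adjusted p = 6.48e-05) and lower in 3, with 1 higher and 7 lower with library totals, 0 called without either D2 2C-negative library, 13 higher and 4 lower of 44 (median 0.21 against 0.79) without D2 2C-positive replicate 1, and 32 and 6 without replicate 2. Mean levels in sgGFP as a share of those in D2 2C-positive replicates 1 and 2, which lay far apart, were 6.45% and 11.2% for SynDux, 1.66% and 4.01% for TdTomato, 2.30% and 5.09% for Duxf3, 16.4% and 42.1% for Zscan4c, 5.83% and 14.0% for Zfp352, 27.6% and 51.0% for Gm5662 and 15.8% and 24.8% for MERVL-int, while BB287469 stood at 274% and 1060%.

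The 2C-positive libraries put 39.7% (D1) and 45.6% (D2) of uniquely mapped reads outside annotated exons, against 9.77% to 15.8% in the other 6 libraries. Genomic DNA spread evenly over the genome would put opposite-strand reads on silent receptor genes, but the median of 1396 olfactory and vomeronasal receptor genes carried 0% of the even-spread rate, where that rate gave 2.29 to 4.47 reads in the 2C-positive libraries, which argues against evenly spread genomic DNA as the whole cause. Pooled over these genes the rate was 8.95% to 14.5% of the even spread there and 6.39% to 10.1% in the other libraries, so a lesser part from DNA stays open. The sgGFP libraries, whose 2C-like genes were above D4, had a share 5.11 points above D4 2C-negative, but their tables differ in other ways, so the 2C-like state and the making of the libraries cannot be told apart. Transcription outside exons in 2C-like cells may add to the share and stays open, untested.

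D2 2C-negative libraries held 2C-like transcripts above D4 2C-negative ones. If a few 2C-positive cells of average TdTomato level, or their reads, had been carried over, TdTomato would keep the same share of its D2 2C-positive level as the 2C-like list. Its share was 0.0757% to 0.816% in the 4 pairs of libraries, against list medians of 1.10% to 3.49%, and at most 0.657 of the list's 10th percentile. That argues against carry-over of such cells or reads as the whole cause. Cells with 2C-like transcripts and little TdTomato stay open. The labels do not say how 2C-positive and 2C-negative cells were told apart. If TdTomato was used, carried-over cells would be low in it by selection, and these shares could not show them. SynDux kept 1.55% to 3.14% of its level, between the list's 10th and 90th percentiles in all 4 pairs, so Dux transgene RNA remaining in 2C-negative cells may account for part of the pattern. Carry-over of 2C-positive cells would give such a share too, so SynDux cannot tell these explanations apart.

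Of 933 repeat subfamilies, 694 were higher in sgGFP than in D4 2C-negative cells, and 193 on the repeats' own scale. Reads in the repeat table per multimapping or exon-free read of the gene table were 1.41 in both sgGFP libraries and 0.578 to 0.731 in the other 8 libraries, so a repeat table made from a larger part of the library may account for the broad shift. Of genes with at least 10 counts in both libraries of 1 group and 0 in the 8 other libraries, 11 were confined to sgGFP, among them mt-Atp6, mt-Atp8, mt-Co2 and mt-Co3, and 0 to 1 to each of the other groups. On the repeats' own scale, which removes a shift of all subfamilies alike, MERVL-int (3.31) and MT2_Mm (2.71) stayed higher, each by at least 2.46 after taking off 2 SE, which argues against that shift as the whole cause for these 2. A rise of both beyond the other subfamilies stays open, as does a table that favours some subfamilies, since how sgGFP tables were made is not given in the sources used here.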
